A study of Rattus norvegicus with 12 samples.

How the data were processed

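Rat extraembryonic endoderm (XEN) cells of the Fisher strain are a cell line with features of the early yolk sac endoderm. Per the labels, total RNA from these cells was treated with DNase, labelled with biotin through a whole-transcript terminal labelling kit and hybridised to Affymetrix rat gene arrays, 1 array per sample. The 12 arrays form 4 groups of 3. Control cells received no compound. The CHIR group received 3 µM CHIR99021, an inhibitor of the kinase GSK3 that stabilises beta-catenin, for 2 days. The forskolin group received 10 µM forskolin, an activator of adenylate cyclase, for 1 day. The combination group received 3 µM CHIR99021 for 2 days with 10 µM forskolin over the last 1 day. All cells spent the last day in low-serum medium. The labels speak of 3 parallels per condition and say nothing of separate cultures, so the p-values measure the spread between these samples, which may be technical. Every sample was grouped by its label.

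The deposited values are on a log2 scale, already summarised and normalised between arrays by the authors, 1 value per probe set and array. The submitters' processing notes name RMA, which corrects background, normalises by quantiles and summarises probes, and the program Partek. Their versions, options, annotation and genome build are not given in the sources used here. The labels do not state the log base. Log2 was taken from the range of the values, whose medians lay between 7.76 and 7.86 on the 12 arrays. Values are not centred per probe set. RMA values are compressed near background, so differences of dim genes are understated, and no detection call was used. As a reference for background, chosen after seeing the data, the 59 measured olfactory receptor genes had a median of 5.83 and a 95th percentile of 6.57. A gene below that 95th percentile in all groups is called near background. Of the genes tested, 10114 lay above it in at least 1 group mean. Precision is limited by the number of arrays, 3 per group.

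The table held 211195 probe sets at the exon level. The platform's probe annotation, from 2010, gave 172924 of them 1 gene symbol and 1661 several symbols, which were left out. The remaining 36610 were unnamed here and entered only a separate count. Symbols were updated through the gene table of the rat assembly GRCr8, used for names alone. Of the 16633 genes, 12878 symbols were current, 3659 were updated and 96 were kept as in that annotation. The value of a gene was the median of its probe sets (median 8 and at most 167 per gene, 1788 genes with 1). A median over probe sets can hide a change limited to part of a gene. No genome coordinates were used.

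Gene values were fitted with limma 3.58.1 in R 4.3.3 (files read with version 1.17.8 of data.table), with a model of 4 group means over all 12 arrays and empirical Bayes moderation without trend. Tests are two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the 16633 genes of each comparison, with a threshold of 0.05. There were 7 comparisons, each treatment and the combination against control, the combination against each single compound, CHIR against forskolin, and the interaction. The interaction is the effect of forskolin with CHIR minus its effect without CHIR on the log2 scale. Positive differences mean that the group named first was higher.

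Before the data were examined, 22 gene lists were fixed, with 469 entries, of which 417 were measured under their name. They cover parietal endoderm, visceral endoderm, anterior visceral endoderm, the extraembryonic endoderm core, Wnt/beta-catenin targets, cAMP/PKA/CREB targets, PTHrP and adenylate cyclase pathway components, epithelial genes, mesenchymal genes, extracellular matrix and its enzymes, cell cycle, cholesterol synthesis, endoplasmic reticulum chaperones, lysosome and endocytosis, glycolysis and hypoxia, TGF-beta and BMP signalling, heat shock and stress, and 5 other cell types (pluripotent cells, trophoblast, mesoderm with definitive endoderm, fibroblasts, endothelium with blood). The list of endoplasmic reticulum chaperones, called chaperones below, also holds other genes of the unfolded protein response, such as Ddit3, Trib3 and Herpud1. Some genes stand in more than 1 list. Each list was tested with camera from limma at a preset correlation between genes of 0.01, which compares its members with all other genes, and p-values were adjusted over the 22 lists of a comparison. Camera was repeated with the correlation estimated from the data. Counts of members are given over all genes and adjusted over the list alone. Beside a count of 0, the number marked unadjusted is the count at an unadjusted limma p under 0.05.

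The genes named for a comparison were set by a rule fixed before the data were examined. It takes the 8 largest rises and the 8 largest falls among genes past the threshold whose 3 arrays in one group all lay above the 3 of the other and whose higher group mean was at or above the median of all gene means (7.48). It adds up to 4 members of each list described, by size of difference, and a fixed set of marker genes whatever their values. Other members of a list that are named to spell out a small count were chosen after their values were seen.

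The alternatives were the mean or the brightest probe set in place of the median, each probe set on its own, a filter on dim genes, quantile normalisation or median centring on top of the authors' values, a variance trend with robust moderation, array weights, a fit to the compared groups alone, a block for the replicate number, an added threshold of 1 on the log2 difference, an estimated correlation or fry in place of camera, bright members alone, and leaving out each array. Leaving out arrays for the cell cycle and epithelial lists, and the parietal list without Vim (with the preset and an estimated correlation), were chosen after seeing the data. Comparisons that share control arrays were set beside 100 simulations of unchanged groups. Arrays of a group were not duplicates, with 0 identical pairs.

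The steps were tested on simulated data over the 16633 genes with 200 changed genes per comparison. For CHIR against control, 61.2%, 94% and 100% of genes changed by 0.5, 1 and 2 log2 units were recovered, and 6.59% of calls were false. For forskolin against control the shares were 65.7%, 95.5% and 100%, with 6.95% false calls. For the interaction they were 25.8%, 86.6% and 98.5%, with 6% false calls. A list shifted by 0.4 log2 units in the forskolin comparison was found and 0 of 20 other lists were called. The noise was drawn for each gene on its own and the lists at random. False calls of lists whose genes vary together were thus not tested. The data gave more than 200 calls in each of these comparisons, so the adjusted threshold was less strict there. The shares recovered in the data may therefore differ. The exon-level step recovered 200 of 200 genes among 3000, with 10 false calls. All its simulated probe sets had the same mean signal before the change, so false calls from dim probe sets were not tested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.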

Results

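Gene expression was compared in rat XEN cells, a stem cell line of the extraembryonic endoderm, under 4 conditions with 3 arrays each. The cells can take on features of parietal endoderm, a migratory cell type that lays down basement membrane, or of visceral endoderm, an absorptive epithelium. The series asks how activation of adenylate cyclase, which acts downstream of the PTHrP receptor, and activation of Wnt/beta-catenin signalling by CHIR99021 (CHIR) move the cells between these fates. Values are deposited log2 signals summarised to 16633 genes, given as mean ± SD with n = 3 arrays per group, and differences are limma estimates. Array medians over all probe sets lay between 7.76 and 7.86. Correlations between arrays were 0.995 to 0.997 within groups and 0.966 to 0.990 between groups, and the first 2 principal components held 56.6% and 19.5% of the variance. The p-values describe the spread between the 3 samples of a group, which are not stated to be separate cultures.

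CHIR against control shows the effect of GSK3 inhibition alone. Axin2, a feedback inhibitor in the Wnt pathway, rose from 5.75 ± 0.15 to 8.64 ± 0.08, a log2 difference of 2.89 (SE 0.142, adjusted p = 2.78e-09). Lgr5, a receptor for R-spondins, rose from 5.47 ± 0.05 to 9.39 ± 0.15, by 3.92 (SE 0.134, adjusted p = 1.1e-10), and the transcription factor Tcf7 by 3.50 (adjusted p = 8.65e-10). Vim, the intermediate filament of migratory cells, fell from 13.16 ± 0.12 to 8.78 ± 0.63, a difference of -4.38 (SE 0.216, adjusted p = 2.78e-09). Plat, the tissue plasminogen activator made by parietal endoderm, fell from 11.14 ± 0.07 to 8.79 ± 0.24, a difference of -2.35 (SE 0.111, adjusted p = 1.83e-09). The largest rises under the naming rule were Ccl24 (4.65), a chemokine, Lgr5, Pbld1 (3.89), Cited1 (3.56), Tcf7, Lbp (3.41), Igf1 (3.35) and Mmp15 (3.18). The largest falls were Tfec (-5.58), a transcription factor, Vim, Tmem63c (-4.26), Cubn (-4.19), an endocytic receptor of visceral endoderm, Gpm6b (-3.71), Lmo1 (-3.71), Cttnbp2 (-3.51) and the receptor kinase Ret (-3.43). With CHIR, Tfec (5.80) and Gpm6b (5.99) lay below the same reference, so their falls may be understated. Of the 16633 genes, 4677 (28.1%) changed, 2373 higher and 2304 lower, and 795 of them changed by at least 1 log2 unit.

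The parietal endoderm list fell with CHIR. Of its 15 measured members, 13 fell and 1 rose over all genes, with 13 and 1 adjusted over the list alone. The median log2 difference was -0.72 (camera adjusted p = 1.21e-09, adjusted p = 0.0447 with an estimated correlation). The members that fell furthest were Vim, Plat, the basement membrane gene Nid1 (-2.04) and Thbd (-1.39 (adjusted p = 4.75e-07)), which encodes thrombomodulin, a surface marker of parietal endoderm. Snai1, which represses E-cadherin, fell by less (-0.41 (adjusted p = 0.00119)), and so did Pth1r (-0.63 (adjusted p = 3.74e-05)), the PTHrP receptor. The member that rose was Fst (0.65). With the brightest probe set of each gene the list median was -0.365 (camera adjusted p = 6.33e-07). Without Vim, an alternative chosen after seeing the data, it was -0.678 (camera adjusted p = 2.22e-08), and with an estimated correlation as well the call was lost (adjusted p = 0.0697). Lama1 fell (-0.27 (adjusted p = 0.0118)), a call that was lost without Control replicate 3 (-0.25, adjusted p = 0.0524). Sparc, also of the parietal list, differed by -0.14 (adjusted p = 0.169) and did not pass.

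Members of the visceral endoderm list went both ways under CHIR. Over all genes and adjusted over the list alone, 5 of 27 measured members rose, namely Ihh (1.52), Lrp2 (1.43), Cdh1 (1.31 (adjusted p = 9.53e-08)), Hnf4a (1.25 (adjusted p = 8.14e-06)) and Cldn6 (0.92), some of which were chosen after their values were seen. Hnf4a encodes a nuclear receptor of visceral endoderm and liver, and Cdh1 encodes E-cadherin. Likewise, 3 fell, namely Cubn, Bmp2 (-1.42) and Amn (-1.15), and Amn and Cubn encode partners of the same uptake receptor. The list had a median of 0.009 and a mean of -0.010 and was not shifted against other genes (camera adjusted p = 0.688). Of its members, 13 lay above the background reference in at least 1 group. The secreted markers Afp (-0.15, control 5.76 ± 0.18) and Ttr (-0.15, control 6.40 ± 0.12) lay near background and did not pass, nor did Foxa2 (0.04). The anterior visceral endoderm list was not shifted (2 rose and 4 fell of 13, camera adjusted p = 0.696). Its member Cer1 (-0.21) lay near background and did not pass, except without Control replicate 2 (-0.29, adjusted p = 0.0499).

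Epithelial genes and cell cycle genes were higher with CHIR. Of the 23 measured epithelial genes, 12 rose and 0 (0 unadjusted) fell over all genes, with 13 and 0 adjusted over the list alone. They were led by the tight junction gene Cldn7 (2.19), Cdh1, the splicing regulator Esrp2 (1.18) and Cgn (1.01), and the list median was 0.31 (camera adjusted p = 8.76e-07, adjusted p = 0.0134 with an estimated correlation). Of the 29 measured cell cycle genes, 23 rose and 1 (Ccne1, -0.39) fell, with 24 and 1 adjusted over the list alone. The replication licensing gene Cdc6 (1.56), the mitotic checkpoint kinase gene Bub1b (0.89), Kif11 (0.76) and Ccne2 (0.72) rose most, and the list median was 0.48 (camera adjusted p = 1.21e-09, adjusted p = 0.0134 with an estimated correlation). Of 20 Wnt/beta-catenin targets, 9 rose, led by Lgr5, Tcf7, Axin2 and Bmp4 (2.37). Another 3 fell, Myc (-1.47), Ephb3 (-1.20) and Dkk1 (-0.36), and the counts were 9 and 3 adjusted over the list alone. That list's median was 0.15 (camera adjusted p = 0.00533, adjusted p = 0.0765 with an estimated correlation). Lef1 (0.08) lay near background and did not pass.

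Other lists fell with CHIR at the preset correlation of camera and did not pass with an estimated correlation. Of 22 genes of endoplasmic reticulum chaperones and the unfolded protein response, 13 fell and 0 (0 unadjusted) rose (15 and 0 adjusted over the list alone). The falls were led by Sdf2l1 (-1.45) and Herpud1 (-0.81), and the list median was -0.39 (camera adjusted p = 8.76e-07, adjusted p = 0.091 with an estimated correlation). Of 27 matrix genes, 14 fell and 3 rose (15 and 3 adjusted over the list alone), with Col6a2 (-2.06), Ccn1 (-1.79) and Ccn2 (-1.58) among the falls, and the list gave camera adjusted p = 6.17e-05 and adjusted p = 0.0697 with an estimated correlation. Of 23 cAMP/PKA/CREB targets, 9 fell and 2 rose (10 and 2 adjusted over the list alone), including the nuclear receptor genes Nr4a3 (-1.56) and Nr4a1 (-1.37), with camera adjusted p = 0.00793 and adjusted p = 0.138 with an estimated correlation, and Crem (-0.13) did not pass. Of 11 core extraembryonic endoderm genes, 6 fell and 2 rose (camera adjusted p = 0.0153, adjusted p = 0.29 with an estimated correlation), with Dab2 (-1.07), Gata6 (-0.59), Sox7 (-0.29) and Sox17 (-0.28) lower and Gata4 (-0.05) not passing. Of 13 mesenchymal genes, 6 fell and 0 (0 unadjusted) rose (camera adjusted p = 0.0164, adjusted p = 0.138 with an estimated correlation), with a mean of -0.66 set by Vim and Tagln (-2.31) and a median of -0.004. Of 21 lysosomal genes, 9 fell and 3 rose (camera adjusted p = 0.0491, adjusted p = 0.317 with an estimated correlation).

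The remaining lists were not shifted by CHIR. Counts of members that rose and fell over all genes were 2 and 6 of 28 for PTHrP and adenylate cyclase components (camera adjusted p = 0.345), where Gnas, near background, rose (0.90) and Pthlh (-0.05) did not pass. They were 4 and 8 of 25 for TGF-beta and BMP signalling (adjusted p = 0.488), 3 and 3 of 17 for cholesterol synthesis (adjusted p = 0.688), 3 and 3 of 22 for glycolysis (adjusted p = 0.488), and 4 and 3 of 15 for heat shock (adjusted p = 0.368). Among markers of other cell types, 3 of 14 trophoblast genes rose, Cdx2 (2.16), Gata3 (1.85) and Igf2 (1.21), and 2 fell (adjusted p = 0.488). The pluripotency list had 2 rises and 3 falls of 12 (adjusted p = 0.971), with Pou5f1, which encodes Oct4, lower (-1.46 (adjusted p = 2.04e-05)). The mesoderm list had 1 and 0 (0 unadjusted) of 12 (adjusted p = 0.971), the fibroblast list 1 and 1 of 14 (adjusted p = 0.775), and the endothelial and blood list 2 and 3 of 14 (adjusted p = 0.47). Median and mean differed in sign for the anterior visceral (-0.071 and 0.034), TGF-beta and BMP (0.004 and -0.12), pluripotency (0.077 and -0.076) and mesoderm (-0.009 and 0.002) lists. None of these lists of other cell types passed camera in any of the 7 comparisons, and neither did the anterior visceral endoderm, PTHrP, cholesterol and heat shock lists.

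**Figure D1:**
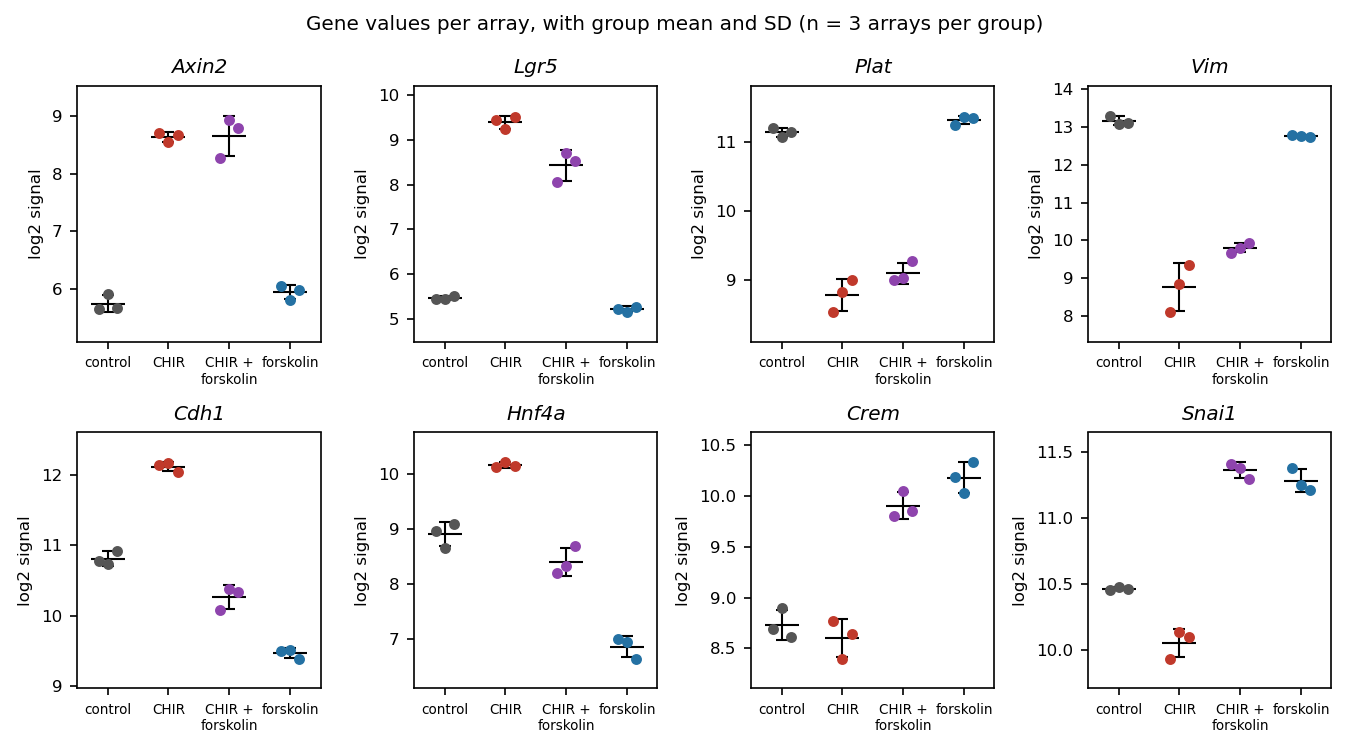
Log2 signal of 8 genes on each of the 12 arrays (points) with group mean and SD (n = 3 per group, x axis the group, y axis log2 signal). Axin2 and Lgr5 were higher in both groups with CHIR, Plat and Vim were lower in both, and Cdh1 and Hnf4a were lower with forskolin than in control and higher with CHIR alone.

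Forskolin against control shows the effect of adenylate cyclase activation alone. Crem, a cAMP-responsive transcription factor gene, rose from 8.73 ± 0.15 to 10.18 ± 0.15, a log2 difference of 1.45 (SE 0.118, adjusted p = 1.25e-06). The kinase gene Sik1 (2.37 (adjusted p = 7.44e-09)) and the nuclear receptor genes Nr4a2 (1.92) and Nr4a3 (1.83), immediate targets of cAMP signalling, also rose, while Nr4a1 fell (-0.96 (adjusted p = 0.000142)). Hnf4a fell from 8.91 ± 0.22 to 6.87 ± 0.19, a difference of -2.04 (SE 0.138, adjusted p = 2.59e-07), and Cdh1 fell by more than its replicate spread, with a difference of -1.35 (SE 0.093, adjusted p = 3.14e-07). Snai1, a repressor of Cdh1, rose (0.82 (SE 0.079, adjusted p = 6.54e-06)). The largest rises were Duoxa2 (4.38), a maturation factor of a dual oxidase, Clps (3.52), the channel gene Trpm2 (3.25), Ttll9 (3.15), the serotonin receptor gene Htr1b (2.97), Trh (2.86), Rasgrf1 (2.73) and Cited1 (2.63). The largest falls were Tnnc1 (-3.04), Nexn (-2.74), Ajuba (-2.54), Rfx6 (-2.52), Capn6 (-2.39), Tagln (-2.27), Bmp3 (-2.25) and Dnmt3b (-2.22), and Tnnc1, Nexn and Tagln encode proteins of the contractile or actin apparatus. In all, 2492 genes changed, 1009 higher and 1483 lower, and 296 changed by at least 1 log2 unit. With each array centred on its median the split was 1202 higher and 1167 lower.

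Epithelial genes fell with forskolin, and the visceral endoderm list was lower at the preset correlation. Of 23 epithelial genes 14 fell and 0 (0 unadjusted) rose, with 15 and 0 adjusted over the list alone, led by Cldn6 (-1.79), Ocln (-1.52), Cdh1 and Krt18 (-1.32). The median was -0.57 (camera adjusted p = 2.09e-11, adjusted p = 0.00193 with an estimated correlation). Of 27 visceral endoderm genes 7 fell and 0 (0 unadjusted) rose, with the same counts adjusted over the list alone. These were Hnf4a, Cldn6, Amn (-1.39), Cdh1, Cubn (-1.29), Bmp2 (-1.08) and Epcam (-0.72), and the list median was -0.10 (camera adjusted p = 0.00364, adjusted p = 0.0558 with an estimated correlation). Cldn6, Cdh1 and Epcam stand in the epithelial list too, so the shifts of the 2 lists are not separate results. Of the 27 members, 13 lay above the background reference in at least 1 group. With the mean of a gene's probe sets the visceral median was 0.01 while camera still placed the list lower (adjusted p = 0.0299). It was -1.08 over bright members alone, and -0.052, -0.049 and -0.059 without Control replicates 1 and 2 and Forskolin replicate 2. The parietal endoderm list was not shifted by forskolin (median 0.065, camera adjusted p = 0.371). In it Snai1 rose and Nid2 fell (-0.48) over all genes, 3 rose and 1 fell adjusted over the list alone, and Plat (0.18 (adjusted p = 0.36)), Thbd (0.07 (adjusted p = 0.774)), Vim (-0.40 (adjusted p = 0.282)), Lama1 (0.06), Sparc (0.12) and Pth1r (0.02) did not pass. In control, Lama1, Sparc and Vim already had means of 13.58, 13.58 and 13.16, and Plat and Thbd had 11.14 and 9.60. Whether a signal ceiling hid a rise of the brightest members was not tested.

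Targets of cAMP signalling rose and cell cycle genes fell with forskolin at the preset correlation. Of 23 cAMP/PKA/CREB targets 10 rose, led by Sik1, Pde10a (2.14), Nr4a2 and Nr4a3, and 3 fell, Gem (-1.25), Nr4a1 and Tent5a (-0.94). The counts were 11 and 3 adjusted over the list alone (median 0.16, camera adjusted p = 0.00316, adjusted p = 0.152 with an estimated correlation). Of 29 cell cycle genes 14 fell, including Cdc20 (-0.72), Cdk1 (-0.63) and Ccne1 (-0.58), and Ccne2 rose (0.45), with 16 and 1 adjusted over the list alone (median -0.30, camera adjusted p = 0.000137, adjusted p = 0.0839 with an estimated correlation). No other list was shifted. Among Wnt/beta-catenin targets 4 rose and 3 fell, Ccnd1 (-2.09), Myc (-1.59) and Dkk1 (-1.38) (camera adjusted p = 0.873). Matrix genes had 6 rises and 5 falls (median -0.031, camera upward, adjusted p = 0.873), with the urokinase gene Plau higher (1.52). Of the core genes Sox7 (0.73 (adjusted p = 7.57e-06)) and Cited2 (0.32) rose and Foxq1 (-1.96) fell, while Gata4 (0.08), Gata6 (0.19) and Sox17 (-0.01) did not pass. Axin2 (0.20), Lef1 (0.10), Pthlh (0.01), Afp (-0.14), Ttr (0.13), Foxa2 (-0.33), Cer1 (-0.10) and Pou5f1 (0.39) did not pass either.

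**Figure D2:**
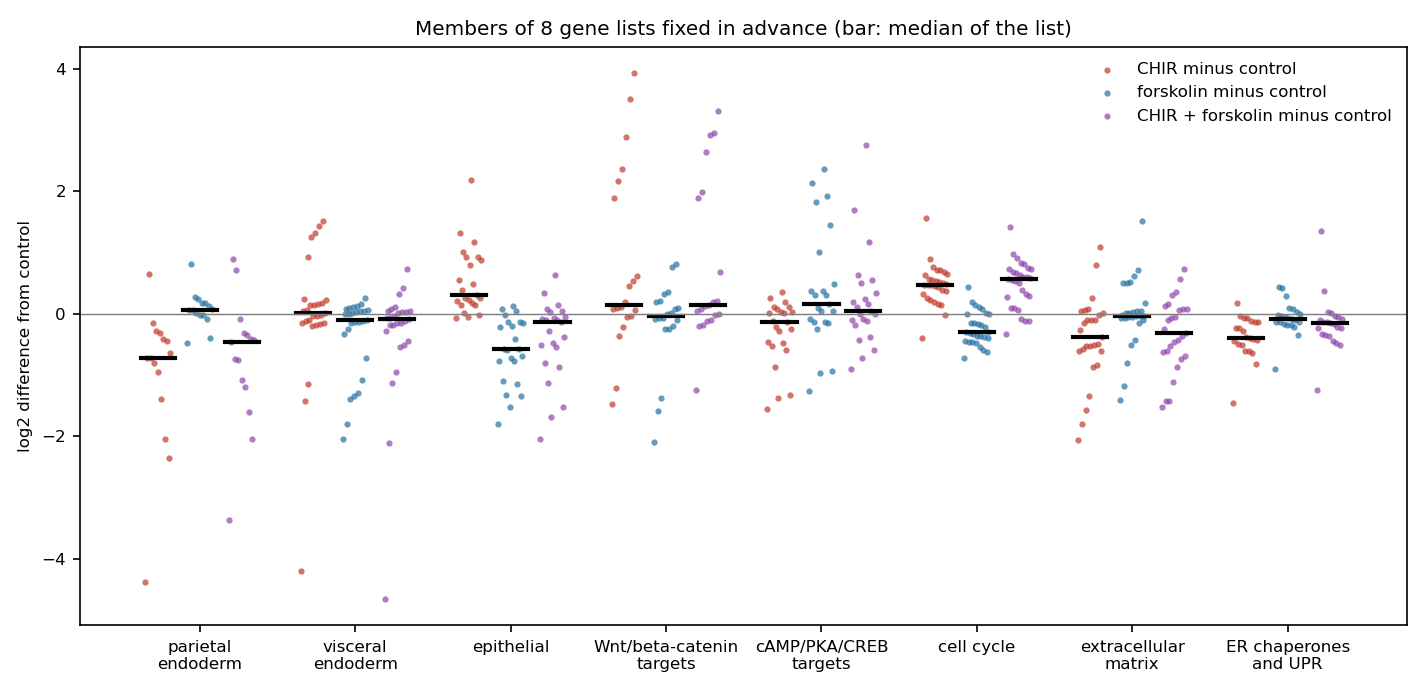
Log2 differences against control (y axis) of the members of 8 gene lists (points) and their medians (bars) for CHIR, forskolin and both (3 arrays per group). The parietal list lies below 0 with CHIR (median -0.72) and near 0 with forskolin (0.07), and the epithelial list lies above 0 with CHIR (0.31) and below 0 with forskolin (-0.57).

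CHIR set directly against forskolin compares the 2 treatments of the series with each other. CHIR was given for 2 days and forskolin for 1 day, so pathway and length of exposure cannot be told apart in this comparison. Genes of the parietal list were lower with CHIR than with forskolin, including Plat (-2.53 (SE 0.111, adjusted p = 5.35e-10)), Vim (-3.99 (SE 0.216, adjusted p = 4.17e-09)) and Thbd (-1.46 (SE 0.115, adjusted p = 1.92e-07)), and so was Snai1 (-1.23). Hnf4a (3.29 (SE 0.138, adjusted p = 3.33e-10)) and Cdh1 (2.66 (SE 0.093, adjusted p = 5.86e-11)) were higher with CHIR, as was Axin2 (2.69). The genes furthest above forskolin were Atp1b1 (5.03), a sodium pump subunit, Ccl24 (4.49), Trpm6 (4.47), Pbld1 (4.40), Mmp15 (4.26), Lgr5 (4.18), the imprinted RNA H19 (3.88) and Igf1 (3.82). Those furthest below were Duoxa2 (-5.67), Tfec (-5.17), Insrr (-4.75), Tmem63c (-4.40), Tshr (-4.33), Gpm6b (-4.26), Trpm2 (-4.21) and Sema3c (-4.16). Of all genes, 5852 (35.2%) differed, 3241 higher with CHIR and 2611 lower, and 1156 differed by at least 1 log2 unit. Of the fixed markers, Crem (-1.58), Pth1r (-0.65), Pou5f1 (-1.85), Gata6 (-0.78), Sox7 (-1.02), Sox17 (-0.28), Lama1 (-0.33) and Sparc (-0.26) were lower with CHIR. Lef1 (-0.02), Pthlh (-0.06), Afp (-0.01), Cer1 (-0.11) and Gata4 (-0.13) did not pass.

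Of 15 parietal endoderm genes 14 were lower with CHIR than with forskolin and 1, Fst (0.67), was higher, with 14 and 1 adjusted over the list alone (median -0.71, camera adjusted p = 3.33e-09, adjusted p = 0.0402 with an estimated correlation). Of 23 epithelial genes 18 were higher and 0 (0 unadjusted) lower (19 and 0 adjusted over the list alone, median 0.86, camera adjusted p = 6.52e-12, adjusted p = 0.00181 with an estimated correlation), led by Cldn7 (2.97) and Cldn6 (2.71). In the cell cycle list 26 of 29 were higher and 0 (0 unadjusted) lower (27 and 0 adjusted over the list alone, camera adjusted p = 5.19e-12, adjusted p = 0.00648 with an estimated correlation), led by Cdc6 (1.70) and Cdk1 (1.34). The visceral list had 7 members higher with CHIR and 2 lower (Cubn, -2.90, and Ttr, -0.28) of 27 and was not shifted (camera adjusted p = 0.0988). Wnt targets were higher (9 against 2, camera adjusted p = 0.000365, adjusted p = 0.0402 with an estimated correlation), including Ccnd1 (2.63). Targets of cAMP signalling were lower (11 against 2 higher, camera adjusted p = 0.000194, adjusted p = 0.055 with an estimated correlation), led by Sik1 (-3.69). Matrix genes (16 lower, 3 higher, adjusted p = 0.000115, adjusted p = 0.055 with an estimated correlation), chaperones (9 and 0 (0 unadjusted), adjusted p = 0.000182, adjusted p = 0.155 with an estimated correlation), mesenchymal genes (6 and 0 (0 unadjusted), adjusted p = 0.00262, adjusted p = 0.0672 with an estimated correlation) and core genes (7 and 2, adjusted p = 0.0142, adjusted p = 0.242 with an estimated correlation) were lower with CHIR. The differences of Ttr (without Forskolin replicate 3, -0.24, adjusted p = 0.0596), Nr4a1 (-0.41 (adjusted p = 0.0243)) and Foxa2 (0.38 (adjusted p = 0.0408)) were lost on leaving out an array. For Nr4a1 these were CHIR replicate 1 and Forskolin replicate 2 (-0.35 to -0.33), and for Foxa2 CHIR replicates 1 and 2 and Forskolin replicates 1 and 3 (0.24 to 0.40).

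Both compounds against control gave rises of Emp1 (4.79 (SE 0.092, adjusted p = 8.57e-13)), a membrane protein gene, Jade1 (3.70), Ccl24 (3.63), the growth factor gene Bmp4 (3.31), Lbp (3.14), Lgr5 (2.96), Axin2 (2.91 (SE 0.142, adjusted p = 2.96e-09)) and Niban1 (2.90). The largest falls were Tfec (-4.89), Cubn (-4.65), the Wnt antagonist gene Sfrp1 (-3.90), Nexn (-3.57), the DNA methyltransferase gene Dnmt3b (-3.55), Cttnbp2 (-3.51), Tnnc1 (-3.47) and Capn6 (-3.46). With both compounds Tfec, Sfrp1, Nexn, Dnmt3b and Tnnc1 lay below the same reference, so their falls may be understated too. Plat (-2.04 (SE 0.111, adjusted p = 8.26e-09)), Vim (-3.35 (SE 0.216, adjusted p = 4.31e-08)) and Thbd (-1.07) fell while Snai1 rose (0.90 (adjusted p = 1e-06)). Cdh1 (-0.54 (adjusted p = 0.000446)), Lama1 (-0.31), Pth1r (-0.73), Nr4a1 (-0.58), Pou5f1 (-1.35) and Gata6 (-0.21 (adjusted p = 0.0346)) fell, and Crem (1.17) and Sox7 (0.37) rose. Hnf4a fell (-0.50 (adjusted p = 0.0126)), a call lost without Control replicate 3 or the combination's replicate 1 (-0.41 and -0.40, adjusted p = 0.0632 and 0.0623). The call of Gata6 was lost without any 1 of Control replicates 2 and 3 and the 3 combination arrays (-0.23 to -0.20, adjusted p = 0.0591 to 0.0999). Lef1 (0.15), Sparc (-0.09), Pthlh (-0.01), Afp (-0.15), Ttr (-0.04), Foxa2 (0.05), Cer1 (-0.15), Gata4 (0.08) and Sox17 (-0.13) did not pass. In all, 4821 genes (29.0%) changed, 2379 higher and 2442 lower, and 737 by at least 1 log2 unit. The majority turned under the other scalings, with 2792 higher and 2148 lower with each array centred on its median and 2606 and 2325 with quantile normalisation.

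With both compounds the parietal list fell (12 of 15 lower, Snai1 and Fst (0.72) higher, 12 and 2 adjusted over the list alone), with a median of -0.46 (camera adjusted p = 4.15e-06, adjusted p = 0.108 with an estimated correlation). The cell cycle list rose (21 of 29 higher and 0 (1 unadjusted) lower, 22 and 1 adjusted over the list alone, median 0.56), with camera adjusted p = 7.6e-09 and adjusted p = 0.0343 with an estimated correlation, led by Cdc6 (1.41). The epithelial list was lower than in control (11 fell, Ezr (0.64) rose, median -0.13, camera adjusted p = 0.00236, adjusted p = 0.0711 with an estimated correlation), led by Ocln (-2.04) and Marveld2 (-1.68). Of the visceral list 8 fell and 3 rose, Lrp2 (0.73), Ihh (0.42) and, near background, Apoc2 (0.32) (camera adjusted p = 0.0388, adjusted p = 0.109 with an estimated correlation). Wnt targets rose (7 rose and Myc (-1.23) fell, camera adjusted p = 0.00325, adjusted p = 0.0972 with an estimated correlation). Matrix genes (13 fell, 4 rose, adjusted p = 0.0024, adjusted p = 0.118 with an estimated correlation), chaperones (7 fell, 2 rose, adjusted p = 0.0152, adjusted p = 0.416 with an estimated correlation) and lysosomal genes (9 fell, 2 rose, adjusted p = 0.0388, adjusted p = 0.32 with an estimated correlation) were lower.

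Forskolin added to CHIR was compared with CHIR alone. The tight junction genes Cldn7, from 10.86 ± 0.11 to 7.15 ± 0.13, and Ocln, from 10.63 ± 0.05 to 8.21 ± 0.27, fell, with differences of -3.71 (SE 0.103, adjusted p = 6.58e-11) and -2.43 (SE 0.134, adjusted p = 3.64e-08). Hnf4a (-1.75 (SE 0.138, adjusted p = 1.04e-06)) and Cdh1 (-1.86 (SE 0.093, adjusted p = 1.5e-08)) fell, while Snai1 (1.31 (SE 0.079, adjusted p = 9.97e-08)), Crem (1.30), Nr4a1 (0.79) and Vim (1.03 (adjusted p = 0.00511)) rose. The other large falls were Lrba (-2.55), the growth factor receptor regulator Lrig1 (-2.51), Foxq1 (-2.45), Cdhr2 (-2.42), Lgals9 (-2.32) and Wipf3 (-2.16). The large rises were Duoxa2 (4.00), Ribc2 (3.98), Sema3c (3.03), Sertad4 (2.78), the cAMP phosphodiesterase gene Pde10a (2.64), Jade1 (2.61), Tshr (2.47) and Adra2b (2.43), the last 2 encoding G protein coupled receptors. Plat (0.31 (adjusted p = 0.0859)) did not pass, except without CHIR replicate 3 (0.42, adjusted p = 0.0245), and Thbd (0.32 (adjusted p = 0.0898)) did not pass. Gata6 (0.38) and Sox7 (0.66) rose. Axin2 (0.02), Lef1 (0.08), Lama1 (-0.04), Sparc (0.06), Pth1r (-0.10), Pthlh (0.04), Afp (0.00), Ttr (0.11), Foxa2 (0.01), Cer1 (0.06), Pou5f1 (0.12), Gata4 (0.12) and Sox17 (0.15) did not pass. In all, 2301 genes (13.8%) changed, 1082 higher and 1219 lower, and 254 by at least 1 log2 unit. Here too the majority turned, with 1211 higher and 1097 lower with median centring and 1260 and 1093 with quantile normalisation.

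In the presence of CHIR, forskolin lowered 15 of 23 epithelial genes and raised Ezr (0.39), with 17 and 1 adjusted over the list alone (median -0.67, camera adjusted p = 8.77e-18, adjusted p = 0.00038 with an estimated correlation). Of the visceral list 9 of 27 fell and 0 (2 unadjusted) rose, with 10 and 0 adjusted over the list alone (median -0.048, camera adjusted p = 0.000455, adjusted p = 0.0233 with an estimated correlation). Among those that fell were Epcam (-1.27) and Cldn6 (-1.20), which stand in the epithelial list too. Targets of cAMP signalling rose (10 rose and Tent5a (-0.43) fell, camera adjusted p = 1.49e-05, adjusted p = 0.0451 with an estimated correlation), led by Pde10a and Nr4a3 (2.19). Of the parietal list Snai1, Vim, Nid1 (0.44) and Col4a1 (0.37) rose and 0 (1 unadjusted) fell, with 7 and 1 adjusted over the list alone (median 0.073, camera adjusted p = 0.0194, adjusted p = 0.412 with an estimated correlation). The list of chaperones and unfolded protein response genes rose (6 rose and 0 (0 unadjusted) fell, camera adjusted p = 0.000455, adjusted p = 0.318 with an estimated correlation). It was led by Ddit3 (1.19), which is not a chaperone gene. The glycolysis list passed camera upward (Pdk1 (0.69) and Vegfa (0.31) rose, Slc2a3 (-0.46) fell, adjusted p = 0.0414, adjusted p = 0.226 with an estimated correlation). In limma, 0 of 29 cell cycle genes passed, with 4 higher and 2 lower at an unadjusted p under 0.05 (median 0.031, camera adjusted p = 0.82, fry adjusted p = 0.66).

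CHIR in the presence of forskolin, the combination against forskolin alone, gave rises of Emp1 (4.74 (SE 0.092, adjusted p = 9.66e-13)), Ccl24 (3.47), Atp1b1 (3.46), Mmp15 (3.35), H19 (3.32), Lgr5 (3.21 (SE 0.134, adjusted p = 8.54e-10)), Fhl1 (3.15) and Pbld1 (3.10). It gave falls of Tfec (-4.48 (SE 0.218, adjusted p = 3.23e-09)), Ret (-3.91), Igfbp7 (-3.80), Sfrp1 (-3.43), Trpm2 (-3.41), Cubn (-3.36), Amph (-3.30) and the incretin receptor gene Gipr (-3.18). Axin2 (2.71), Hnf4a (1.54 (SE 0.138, adjusted p = 1.2e-06)) and Cdh1 (0.80 (SE 0.093, adjusted p = 1.41e-05)) rose, and Plat (-2.22 (SE 0.111, adjusted p = 4.17e-09)), Vim (-2.96 (SE 0.216, adjusted p = 1.65e-07)), Thbd (-1.14), Pth1r (-0.75), Lama1 (-0.37), Pou5f1 (-1.74), Gata6 (-0.40) and Sox7 (-0.36) fell. Changes of Nr4a1 (0.38 (adjusted p = 0.0387)), Sparc (-0.21 (adjusted p = 0.0394)) and Foxa2 (0.38 (adjusted p = 0.0425)) were lost on leaving out any 1 of 4, 5 and 5 of the 6 arrays (adjusted p up to 0.156, 0.128 and 0.195). The arrays that could be left out without losing these calls were the combination's replicate 1 and Forskolin replicate 2 for Nr4a1, Forskolin replicate 1 for Sparc and Forskolin replicate 2 for Foxa2. Snai1 (0.08), Crem (-0.28), Lef1 (0.05), Pthlh (-0.02), Afp (-0.01), Ttr (-0.18), Cer1 (-0.05), Gata4 (-0.01) and Sox17 (-0.12) did not pass. Of all genes 4998 (30.1%) changed, 2728 higher and 2270 lower, and 759 by at least 1 log2 unit.

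In that comparison the parietal list fell (13 of 15 fell and Fst (0.74) rose, 13 and 1 adjusted over the list alone, median -0.63, camera adjusted p = 6.84e-08, adjusted p = 0.0766 with an estimated correlation). Cell cycle genes rose (22 of 29 rose and 0 (0 unadjusted) fell, 24 and 0 adjusted over the list alone, median 0.78, camera adjusted p = 2.37e-14, adjusted p = 0.00715 with an estimated correlation), among them Cdc6 (1.56) and Cdk1 (1.45). Wnt targets rose (10 rose, Ephb3 (-0.54) and, near background, Cdx1 (-0.34) fell, camera adjusted p = 8.76e-05, adjusted p = 0.0373 with an estimated correlation), including Tcf7 (2.75) and Bmp4 (2.49). Matrix genes (14 fell, 3 rose, adjusted p = 0.00109, adjusted p = 0.14 with an estimated correlation) and core genes (6 fell, 1 rose, adjusted p = 0.016, adjusted p = 0.35 with an estimated correlation) fell. The epithelial list (8 rose, 5 fell, adjusted p = 0.159) and the visceral list (6 rose, 4 fell, adjusted p = 0.837) were not shifted. Epithelial members that fell here were Cldn7 (-0.75), Marveld2 (-0.58), Ocln (-0.52), Epcam (-0.41) and Tjp1 (-0.40).

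The interaction asks whether forskolin acted differently in the presence of CHIR. Cited1, a transcriptional coregulator gene, was 7.45 ± 0.27 in control, 11.01 ± 0.12 with CHIR, 10.09 ± 0.11 with forskolin and 9.37 ± 0.17 with both, an interaction of -4.27 (SE 0.181, adjusted p = 3.63e-08) on the log2 scale. Cldn7 rose with CHIR and was lower with both than with forskolin alone, an interaction of -2.93 (SE 0.146, adjusted p = 9.93e-08). Tnnc1 fell from 9.74 ± 0.03 to 6.64 ± 0.26 with CHIR, 6.70 ± 0.19 with forskolin and 6.27 ± 0.13 with both, an interaction of 2.68 (SE 0.18, adjusted p = 1.78e-06), and these lower values lie near the background reference of 6.57. The other negative interactions under the naming rule were Rasgrf1 (-2.96), Lbp (-2.78), Trpm2 (-2.45), Pllp (-2.44), Plekhb1 (-2.41) and Fa2h (-2.31). The other positive ones were the phosphatase gene Dusp4 (2.35), Tagln (2.19), Fhl1 (2.08), Spsb1 (1.97), Pkdcc (1.97), the Wnt antagonist gene Dkk1 (1.95) and Rab27a (1.89). Dusp4 too lay near that reference with CHIR (6.05 ± 0.22), forskolin (6.71 ± 0.13) and both (6.73 ± 0.26). Tagln lay not far above that reference, at 7.00 ± 0.16, 7.05 ± 0.10 and 6.93 ± 0.01 in the same order. Among the fixed markers Nr4a1 (1.75 (adjusted p = 4.68e-05)), Vim (1.42 (adjusted p = 0.0112)) and Snai1 (0.49 (adjusted p = 0.0166)) had a positive interaction and Cdh1 a negative one (-0.51 (adjusted p = 0.0327)), the last lost on leaving out any 1 of 7 of the 12 arrays. These were Control replicates 1 and 2, CHIR replicates 1 and 2, the combination's replicate 1 and Forskolin replicates 1 and 2 (-0.50 to -0.42, adjusted p = 0.0615 to 0.0796). Axin2 (-0.18), Plat (0.13), Thbd (0.25), Hnf4a (0.28), Crem (-0.15), Lef1 (-0.02), Lama1 (-0.09), Sparc (-0.07), Pth1r (-0.12), Pthlh (0.03), Afp (0.14), Ttr (-0.03), Foxa2 (0.34), Cer1 (0.17), Pou5f1 (-0.28), Gata4 (0.04), Gata6 (0.20), Sox7 (-0.07) and Sox17 (0.16) did not pass.

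Of the 16633 genes, 1050 (6.31%) had an interaction, 540 positive and 510 negative, and 271 were at least 1 log2 unit in size. With median centring 503 were positive and 540 negative. The count was 1870 with the mean and 630 with the brightest of a gene's probe sets in place of the median. In the main fit, each compound alone lowered 216 of the genes with an interaction, and 213 of these had a positive one. Each alone raised 98, of which 96 had a negative one. In these 213 and 96 genes the combination gave less than the sum of the separate effects, and the cause was not tested. The same control arrays enter both separate effects and, with the opposite sign, the interaction. Their error alone favours opposite signs in genes picked this way, so these splits are no test of a common rule. Over the 5705 genes changed by either compound, the slope of the combined effect on the sum of the separate effects was 0.677 and the correlation 0.871. These are values across genes, which are not independent replicates, and the control arrays enter both sides, so the slope is no test of additivity. Of 23 epithelial genes 10 had a negative interaction and 3 a positive one, Cldn6 (0.59), Krt8 (0.53) and Ezr (0.59), with 10 and 3 adjusted over the list alone (median -0.22, camera adjusted p = 0.000886, adjusted p = 0.0986 with an estimated correlation). Of 29 cell cycle genes 6 had a positive interaction and 0 (0 unadjusted) a negative one, led by Cdk1 (0.73) and Ccna2 (0.57), with 13 and 0 adjusted over the list alone (median 0.29, camera adjusted p = 0.000116, adjusted p = 0.0986 with an estimated correlation). Chaperones (5 positive and 0 (0 unadjusted) negative, led by Sdf2l1, 1.10, median 0.26, adjusted p = 2.27e-05, adjusted p = 0.183 with an estimated correlation) and TGF-beta and BMP genes (Bmp2, 1.54, Id4, 1.16, and Inhba, 1.00, positive, median 0.19, adjusted p = 0.00742, adjusted p = 0.0986 with an estimated correlation) also passed. No other list did.

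**Figure D3:**
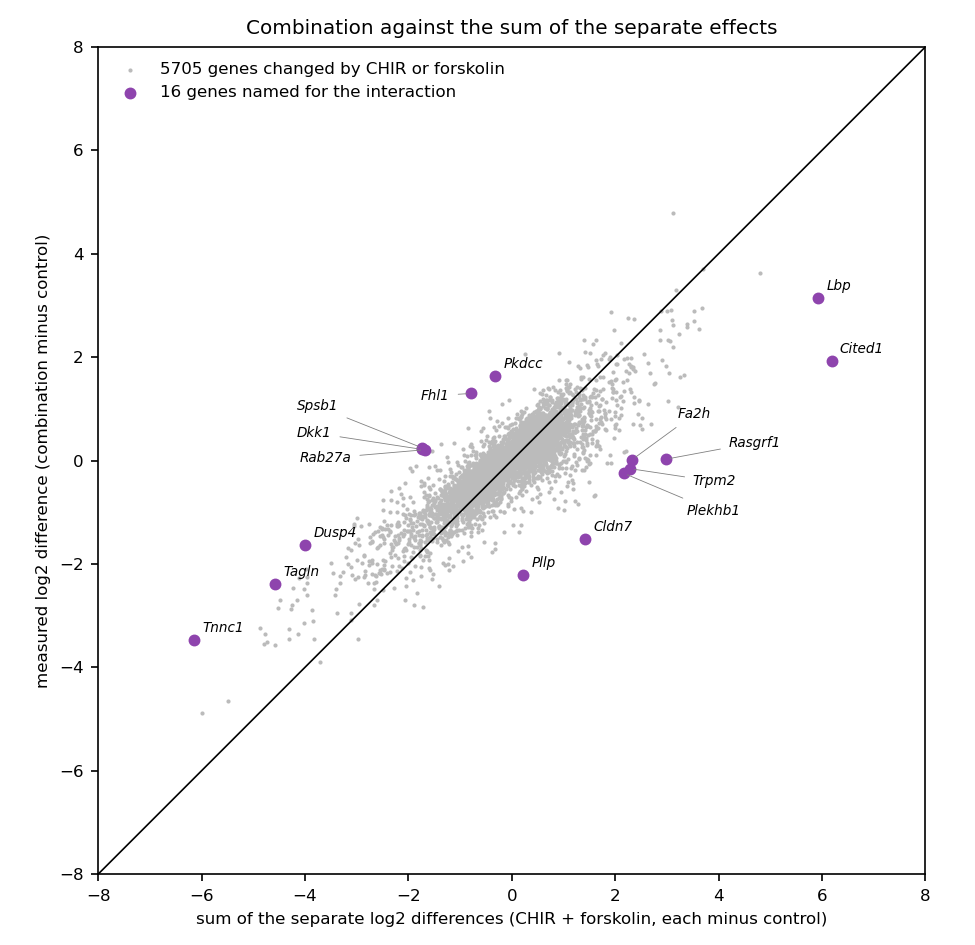
Measured log2 difference of the combination against control (y axis) against the sum of the log2 differences of CHIR and of forskolin against control (x axis) for 5705 genes changed by either compound (grey) and the 16 genes named for the interaction (purple). The line marks equality, from which Cited1 and Lbp lie below and Tnnc1 and Tagln above.

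Effects of a compound were also compared between separate sets of arrays. CHIR changed 3225 genes both against control and in the presence of forskolin, 97.6% of them in the same direction, and the correlation of the 2 effects across genes was 0.768 (Spearman 0.662). Higher in both were 1646 genes, such as Lgr5 and Axin2, against 389.2 from independent lists, and lower in both were 1503, such as Tfec and Plat, against 314.4. Forskolin changed 1040 genes both without and with CHIR, 91.1% in the same direction, with a correlation of 0.483 (Spearman 0.358). Higher in both were 458, such as Duoxa2 and Crem, against 65.6 from independent lists, and lower in both were 489, such as Hnf4a and Cdh1, against 108.7.

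CHIR and forskolin, both set against the same 3 controls, changed 1464 genes in common, 47.3% of them in the same direction. Of these, 204 rose with both (144 from independent lists), among them Cited1 and Lbp, and 488 fell with both (205.4), among them Tnnc1 and Tagln. Higher with CHIR and lower with forskolin were 421 (211.6), including Hnf4a and Cdh1, and lower with CHIR and higher with forskolin were 351 (139.8), including Snai1. The correlation across genes was 0.04, against 0.5 in 100 simulations of unchanged groups, and the covariance 0.006 against 0.0073, a difference of -0.0013. With 3 controls no split leaves at least 2 arrays on each side, so part of the excess in the same direction may come from the shared controls.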

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

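Among the tests in this part, the test of visceral endoderm genes above background and the counts of epithelial genes lower with both compounds than with forskolin alone and of those far above background were chosen after the values were seen. The fry and camera p-values of the tests of explanations in this part were adjusted over 7 tests. With 3 arrays per group no array was tested as an outlier. The entries below are genes and lists whose forskolin effect differed with and without CHIR by the interaction test, and probe sets outside the named genes.

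The fixed markers with a positive interaction were Nr4a1 (1.75), Snai1 (0.49) and Vim (1.42), and Cdh1 had a negative one (-0.51). Among genes named for CHIR, the interaction was negative for Ccl24 (-1.17), Lgr5 (-0.72), Pbld1 (-0.80), Cited1 (-4.27) and Lbp (-2.78), and positive for Tfec (1.11), Tmem63c (1.85), Cubn (0.84), Gpm6b (1.48), Lmo1 (0.79) and Cttnbp2 (1.21). Among genes named for forskolin, it was negative for Clps (-1.87), Trpm2 (-2.45), Htr1b (-1.99), Trh (-1.65) and Rasgrf1 (-2.96), and positive for Tnnc1 (2.68), Nexn (1.01), Rfx6 (0.86), Tagln (2.19), Bmp3 (1.64) and Dnmt3b (1.25). With either compound alone the means of Tnnc1, Bmp3 and Dnmt3b were 6.638 and 6.7, 6.162 and 6.544, and 6.618 and 6.969 (CHIR, then forskolin), near the background reference of 6.57, and a part of a background floor in these was not tested. Further positive interactions were Dusp4 (2.35), Fhl1 (2.08), Spsb1 (1.97), Pkdcc (1.97), Dkk1 (1.95) and Rab27a (1.89), and further negative ones Cldn7 (-2.93), Pllp (-2.44), Plekhb1 (-2.41) and Fa2h (-2.31). Other genes of this paragraph also had a group mean below that reference. With CHIR these included Dusp4 (6.05), Gpm6b (5.99), Tfec (5.80), Trpm2 (5.21) and Fa2h (5.97), and a floor was not tested in them either. The chaperone list had a median interaction of 0.256 and the TGF-beta and BMP list one of 0.185, and both calls were lost with an estimated correlation (adjusted p = 0.183 and 0.0986). Outside the named genes, 1544 unnamed probe sets were higher and 1522 lower with CHIR than in control, 559 higher and 486 lower with forskolin, and 1701 higher and 1682 lower with both, of 36610 tested.

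The fall of epithelial genes under forskolin was larger in the presence of CHIR at the preset correlation, with a median interaction of -0.215 over 23 genes, a call lost with an estimated correlation (adjusted p = 0.0986). Under the 2 other scalings the median was -0.195 (fry adjusted p = 6.44e-05) and -0.229, which argues against an offset between arrays that these scalings remove. The values were already normalised by the authors, so an error that all these scalings share was not tested. A background floor, which would limit the fall of dim genes under forskolin alone, is argued against for Cldn7, Marveld2, Ocln, Epcam and Tjp1, as 5 of the 10 genes with a negative interaction were lower with both compounds than with forskolin alone (median -0.52). It is argued against for Krt19 and Cdh1 too, by their signal alone. With Ocln, Epcam and Tjp1 they make up the 5 of the 10 genes whose control and forskolin means lay at least 1 log2 unit above the median of all genes. The median interaction of these 5 was -0.549, but they were picked among genes with a negative interaction, so its sign was fixed in advance. The forskolin means of Krt19 and Cdh1 were 12.15 ± 0.06 and 9.47 ± 0.07, against the background reference of 6.57. The interaction calls of Cdh1, Epcam, Tjp1 and Krt19 were lost on leaving out 7, 8, 9 and 8 of the 12 arrays (adjusted p up to 0.0796, 0.0887, 0.0786 and 0.0898), with values from -0.703 to -0.363 over all 12 and the 4 genes. The arrays that could be left out without losing the call were Control replicate 3, CHIR replicate 3, the combination's replicates 2 and 3 and Forskolin replicate 3 for Cdh1, and Control replicate 2, CHIR replicate 1, the combination's replicate 2 and Forskolin replicate 1 for Epcam. They were replicate 2 of Control, CHIR and the combination for Tjp1, and Control replicate 2, CHIR replicate 3, the combination's replicate 3 and Forskolin replicate 1 for Krt19. A floor remains open for Cldn4, Esrp2 and Crb3, with forskolin means of 6.16 ± 0.12, 7.76 ± 0.12 and 5.79 ± 0.13, and for the list as a whole. The 11 members at least 1 log2 unit above the median of all genes had a median of -0.035 (fry adjusted p = 0.389) but went both ways, 5 negative and 3 positive, while the 12 dimmer ones had -0.325. The outcome set beforehand as fitting a floor was met by those 11 members, but a median near 0 over members of opposite sign decides nothing, a reading adopted after the value was seen, and a treatment effect may add to a floor.

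At the preset correlation, cell cycle genes fell under forskolin without CHIR and were not shifted by it with CHIR, with a median interaction of 0.287. With an estimated correlation the call of the fall was lost (adjusted p = 0.0839) and so was that of the interaction (adjusted p = 0.0986). A signal ceiling is argued against, because the 21 members whose highest group mean was under 12 had a median of 0.268 (fry adjusted p = 0.000375). An offset between arrays that the other scalings remove is argued against too, with medians of 0.274 (fry adjusted p = 0.000375) and 0.277 under them. That CHIR keeps these genes up against forskolin remains a hypothesis, as 6 of 29 members passed over all genes for the interaction.

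The visceral endoderm list did not shift under CHIR. Members below background could hide a shift, since 13 of 27 lay above the olfactory receptor bound. Those 13 had a median of 0.159 and a mean of 0.013 (95% interval across genes -0.934 to 0.959, camera adjusted p = 0.341). Of them 5 rose and 3 fell past the threshold (Cubn, Bmp2 and Amn), and an average over members that go both ways leaves open whether dim members hide a shift. Whether the treatment moves parts of the visceral program in opposite directions may be asked of these 8 genes, but no other test was run.

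Other splits of the arrays were counted for each comparison. For the interaction, 1 of 100 splits of the 12 arrays, the real one, gave 1050 genes or more and the highest other gave 92. The other splits mix the treatments within groups, which adds the CHIR and forskolin effects to the spread, so low counts were to be expected with or without an interaction and say nothing about the 1050 genes. For the comparisons of 2 groups there are 10 splits of 6 arrays, too few for a share under 0.05. In each, 1 of the 10 splits, the real one, gave the largest count, and the highest other gave 0. The real counts, fitted to the 2 groups alone, were 4203 for CHIR, 2367 for forskolin and 4507 for both against control, 1911 for forskolin with CHIR, 5067 for CHIR with forskolin and 5659 for CHIR against forskolin.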

How the results depend on the processing

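Leaving out arrays for the cell cycle and epithelial lists, and the parietal list without Vim (with the preset and an estimated correlation), were chosen after seeing the data. No called result reversed under any alternative run, though the visceral median under forskolin was 0.01 with the mean of a gene's probe sets, where camera still placed the list lower. Testing each probe set on its own called 32344 for CHIR, 12710 for forskolin, 33854 for both, 11780 for forskolin with CHIR, 36371 for CHIR with forskolin, 3202 for the interaction and 46143 for CHIR against forskolin, of 172924 probe sets in place of 16633 genes. An added threshold of 1 log2 unit left 795, 296, 737, 254, 759, 271 and 1156 genes in the same order. The interaction count was 1870 with the mean and 630 with the brightest of a gene's probe sets, and the cause was not tested. The shift of the visceral list under forskolin (-0.101) lost its call with an estimated correlation (adjusted p = 0.0558), a wider null for genes that vary together. Leaving out 1 array gave 4001 to 4272 genes for CHIR, 1789 to 2227 for forskolin, 4119 to 4523 for both, 1653 to 2180 for forskolin with CHIR, 4255 to 4524 for CHIR with forskolin, 838 to 1007 for the interaction and 5126 to 5370 for CHIR against forskolin, with fewer arrays in each fit. Without Vim the parietal median with CHIR was -0.678 (camera adjusted p = 2.22e-08), a call lost with an estimated correlation as well (adjusted p = 0.0697), a wider null without the member that fell furthest. Leaving out 1 array, the parietal median lay between -0.768 and -0.608 with CHIR and 0.039 and 0.083 with forskolin, and the visceral one between -0.104 and -0.049 with forskolin and -0.033 and 0.046 with CHIR. The cell cycle median lay between 0.47 and 0.492 with CHIR and -0.328 and -0.246 with forskolin, and the epithelial one between 0.308 and 0.354 and between -0.659 and -0.552. With the replicate number as a block (replicate block) the counts were 4581, 2401, 4711, 2175, 4907, 978 and 5768. No pairing by number was seen, as 1 of 18 pairs with the same number correlated above 0.1 (range -0.195 to 0.157) and 4 of 12 arrays were closest to one of their own number. These correlations over all genes cannot exclude a weak pairing or one limited to some genes, and the labels do not say whether equal numbers share a culture. Of 2944 alternative values of named genes 2886 kept their side of the threshold, 48 lost the call, 10 gained it and 0 called values changed sign. Changes of sign among values that passed in neither fit were not counted. Of the losses, 36 came from leaving out 1 array and 4 from the replicate block. Quantile normalisation gave 4, median centring 3 and the mean of a gene's probe sets 1. RMA values are compressed near background, which limits the dim genes. The dim filter is set at the median of all gene means, so the 8776 genes it kept do not measure this limit.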

Other observations

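The gene lists and the exon-level test in this part were chosen after the data were seen, and the genes that prompted a list were left out of its test. Camera p-values of these lists were adjusted over 21 tests. Gene medians can hide changes within a gene, so probe sets were set against the rest of their gene (limma's diffSplice) in 8696 genes. Values are compressed near background, so a dim probe set can differ from the rest of a gene that changed as a whole. How many calls arise this way was not tested. With CHIR 1154 genes passed, 213 of them among the 3787 tested genes without a call at the gene level. The actin-binding gene Lima1 had a gene difference of -0.17 and probe set differences from -0.32 to 4.32 (adjusted p = 2.87e-49), and the calcium channel gene Cacna1d probe sets from -2.26 to 1.43. With forskolin 606 genes passed, 155 of them among 5086 without a gene-level call, such as the actin-binding genes Actn4 (-0.42 to 0.40, adjusted p = 1.1e-19) and Cald1 (-1.56 to 0.49).

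Rsad2 (1.84), Ddx60 (1.41), Trim14 (2.90) and Lgals9 (1.77), known as interferon-stimulated genes, were higher with CHIR than in control and lower when forskolin was added. The hypothesis that this may extend to interferon-stimulated genes as a group was tested on the 24 other measured members. With CHIR 11 rose and 0 (0 unadjusted) fell (median 0.217, camera adjusted p = 4.03e-05, adjusted p = 0.0352 with an estimated correlation). Forskolin added to CHIR lowered 12 and raised 0 (0 unadjusted) (median -0.46, camera adjusted p = 1.2e-08, adjusted p = 0.0132 with an estimated correlation). The median interaction was -0.315 (camera adjusted p = 9.25e-08, adjusted p = 0.0132 with an estimated correlation). The list moved as the hypothesis states, but several members lay near background in all groups. Of these, Ifit1 (0.08), Ifit2 (0.03), Ifit3 (-0.07), Mx1 (0.06) and Oas1a (0.17) did not pass with CHIR, while Ifih1 (0.53) and Cmpk2 (0.47) rose. A response of all interferon-stimulated genes is thus not shown, and no interferon gene or protein was tested.

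Forskolin lowered the cytoskeletal genes Tagln (-2.27), Nexn (-2.74), Fhl1 (-1.85) and Acta1 (-1.75) and also Ankrd1 (-1.88), Ccn2 (-1.41) and Ajuba (-2.54). A hypothesis is that targets of the actin-regulated factors SRF and MRTF fall together. Of 14 other targets 8 fell and 1 rose (Tpm2, 2.03) (median -0.427, camera adjusted p = 0.000261), which is consistent with it, but the call was lost with an estimated correlation (adjusted p = 0.098). CHIR alone also lowered 8 of the 14 and raised 1 (Tpm1, 0.76) (median -0.399, camera adjusted p = 0.000277, adjusted p = 0.098 with an estimated correlation), and forskolin added to CHIR gave a median of -0.01 (camera adjusted p = 0.809). For targets of YAP and TEAD, 7 of 18 other members fell and 3 rose under forskolin (median -0.14, camera p = 0.154 before adjustment, adjusted p = 0.231, adjusted p = 0.394 with an estimated correlation). The outcome set beforehand as counting against lower YAP and TEAD target expression, a p of 0.05 or more, was met. That criterion was wrong, since a missed threshold excludes nothing and more members fell than rose, and the question stays open, a reading adopted after the value was seen. With CHIR alone 7 of the 18 YAP and TEAD targets fell and 2 rose (camera adjusted p = 0.0252, adjusted p = 0.108 with an estimated correlation). With both compounds 9 fell and 3 rose against control (camera adjusted p = 0.0252, adjusted p = 0.108 with an estimated correlation).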
